A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

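Yeast cultures treated with 35 ppm paraquat for 2 h were compared with untreated cultures on 3 2-colour arrays, each scanned at high and low laser power. The deposited values are log ratios of the 2 channels, taken here as log2, and per the labels the authors applied LOWESS normalization to spots with flag 0. Per the labels' descriptions the authors also merged both scans into an averaged column, which was not used here; the description of the high power scan of replicate 1 states the LOWESS step alone. The base of the logarithm and the direction of the ratio are not given in the sources used here, and both were taken from the convention of the repository and the order of the channels. The tests against 0 and the list tests do not depend on the base, while the printed folds, the 2-fold counts and the test against 1.2-fold do. Treated cultures carried Cy5 in all 6 scans, so dye and treatment were confounded. The medians of the scans were 0.01, -0.03, 0.02, 0.02, -0.01 and -0.03, for high and low power of replicates 1, 2 and 3.

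Of 6912 probes, 5513 had 1 gene symbol in the platform annotation, 0 had several and 1399 had none. Symbols of 5508 were updated by gene identifier through the RefSeq table of assembly R64. That table was used for names and for the chromosome of each gene. Probes with identical values in every scan (to 9 decimals) were counted as 1 feature, which joined 78 sets, including 49 ACT1 probes. The 761 probes without a value in any scan were left out. High and low scans of an array were averaged, and the 5693 features with a value on all 3 arrays were tested, 5218 with a gene name and 475 without.

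In R 4.3.3, limma 3.58.1 fitted the mean log2 ratio against 0 (lmFit and eBayes, two-sided, with 2 residual and 19.1 prior degrees of freedom) with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 44 lists, with camera at an estimated correlation and fry as alternatives. Camera compares a list with the other genes, while fry tests whether a list's genes move one way against no change. With the preset correlation camera takes its degrees of freedom from the number of probes. With an estimated correlation, and in fry, they are the 2 residual degrees of freedom of the arrays. Simulated data of the same 5693 features held many changed genes, far more than limma called in the real data. There limma recovered 11.5% of genes changed by 0.5 on the log2 scale, 87.3% at 1 and 100% at 1.5. Beside these it called 10.85 unchanged genes per simulation. More changed genes ease the adjusted threshold, so these shares likely overstate what could be recovered from the real arrays. Camera called 0.05 lists per simulation with no change, on arrays simulated without a shared structure.

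Sample groups, tests, gene lists and the naming rule were chosen before the data were examined. Named genes were the 10 largest mean rises and the 10 largest falls with the same sign on every array, those past the threshold first, the 4 members with the smallest p of each called list, and 15 genes of oxidative and iron metabolism fixed in advance. Alternatives were each scan alone, centring, scaling, stricter and looser filters on missing values, robust and unmoderated variance, a test against 1.2-fold and leaving out each replicate. Removing an additive trend over the digit fields of the probe number, taken as a stand-in for position on the array, testing named probes alone, and filling high power values with low power values were added after seeing the data.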

Results

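The series profiled mRNA of the budding yeast strain S288C after exposure to paraquat (methyl viologen), a compound that cycles electrons to oxygen and so produces superoxide inside cells. Exponentially growing cultures in YPD medium received 35 ppm paraquat for 2 h, and their Cy5-labelled cDNA was hybridised on 2-colour arrays against Cy3-labelled cDNA of untreated cultures. The design text describes 3 hybridisations of independent biological samples. Each array was scanned at high and at low laser power, so that the 6 scans form 3 replicates. A high power scan gave a value for 5730, 6006 and 5946 of the 6912 probes on replicates 1, 2 and 3, and a low power scan for 2496, 2826 and 4076. The number of arrays limits the precision, with a median standard error of 0.20 on the log2 scale per probe.

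FIT2 and GPX2 rose after paraquat, and no gene fell past the threshold. Both calls were lost, by a limma adjusted p, on high power scans alone (0.0647), with arrays centred (0.0667), centred and scaled (0.161), without variance moderation (0.741), with low power values filling gaps (0.0837) and against 1.2-fold. FIT2 (YOR382W), a cell wall mannoprotein that retains iron-carrying siderophores, had a mean log2 ratio of 1.21 ± 0.48 (SD, n = 3 arrays), 2.31-fold, with a limma adjusted p of 0.0432. GPX2 (YBR244W), a glutathione peroxidase, had a mean of 1.09 ± 0.12 (SD, n = 3 arrays), 2.13-fold, also with a limma adjusted p of 0.0432. Signs here take each value as the base 2 logarithm of treated over untreated, which is likely from the order of the channels in the labels and from the repository's convention but is stated in no source; with the opposite direction every rise would be a fall. GPX2 was the 1 gene past 2-fold on each of the 3 arrays, at 1.23, 1.01 and 1.03.

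Among 5693 probes tested, limma called 2 higher and 0 lower. At an unadjusted p under 0.05 the same fits gave 312 higher and 301 lower, against 285 in all by chance. With a trend over the probe numbers removed, limma gave 479 in all at that level, so a part of the excess followed that trend. The trend held 14.1%, 18.6% and 9.85% of the variance on replicates 1, 2 and 3. The sign was the same on all arrays for 1822 probes, or 32.0%, where independent signs give 25%. The count of called probes depended on single arrays, with 0 without replicate 1, 70 without replicate 2 and 8 without replicate 3, and 0 of the 8 were FIT2 or GPX2. With a trend over the probe numbers removed, FIT2 kept its call (limma adjusted p = 0.00975) and GPX2 lost it (mean 0.88, limma adjusted p = 0.218).

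The other genes with the largest mean increases did not pass the threshold. SDD1 averaged 1.08 ± 0.39, IZH4, a membrane protein linked to zinc homeostasis, 1.02 ± 0.37, and APC2, a subunit of the anaphase-promoting complex, 1.01 ± 0.38 (SD, n = 3 arrays). STP4 followed at 0.99, the peroxiredoxin TSA1 at 0.97, YOR338W at 0.95 (0.49 without replicate 1), YLR297W at 0.89 and the thioredoxin TRX2 at 0.89. The largest mean decreases, which did not pass either, belonged to the hexose transporter HXT7 at -0.95 ± 0.38, IRC7 at -0.93 ± 0.69 (-0.53 without replicate 1), the sodium-phosphate symporter PHO89 at -0.92 ± 0.44 and HSU1 at -0.92 ± 0.85 (-0.43 without replicate 1). HXT2, the beta-tubulin gene TUB2, the purine genes ADE13 and ADE17, ICS2 and REE1 lay between -0.91 and -0.87. The arrays were far apart for some of them, with ICS2 at -2.21, -0.24 and -0.18 and TUB2 at -1.80, -0.23 and -0.67 on replicates 1, 2 and 3, so that without replicate 1 their means were -0.21 and -0.45. SDD1, TSA1, YOR338W, HSU1, ICS2 and ADE13 had a value in only 1 scan of each array.

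**Figure D1:**
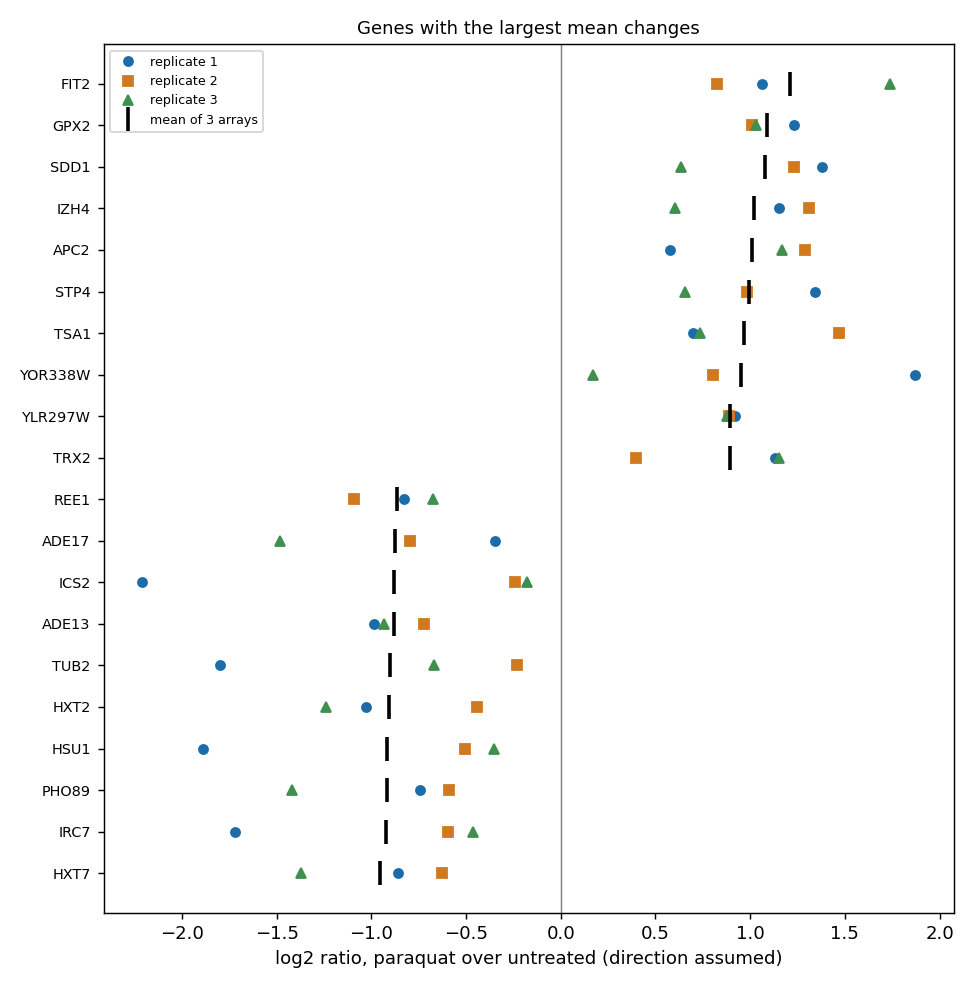
Log2 ratio of each of the 20 genes with the largest mean changes of the same sign on every array (x axis, paraquat over untreated, direction assumed), with 1 symbol per array and a bar for the mean of 3 arrays. FIT2, at 1.06, 0.82 and 1.74, and GPX2, at 1.23, 1.01 and 1.03, passed the threshold and the other genes did not.

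Gene lists were tested for a shift of their mean against other genes. Of 45 lists fixed before the data were examined, 44 had at least 4 measured probes, and camera with a preset correlation of 0.01 called 12, with 4 higher and 8 lower. The list means of peroxide defence, thiol reduction, Yap1 targets and iron uptake were above 0. Those of purine synthesis, general stress, glycogen and trehalose, chaperones, the proteasome, iron-sulfur enzymes, hexose transport and branched-chain amino acids were below 0. The mean of each of the 12 lists had the same sign on all 3 arrays, and no list's median and mean among the 12 differed in sign. With an estimated correlation camera called 0 lists, with a smallest adjusted p = 0.605 with an estimated correlation, while fry, which tests each list against no change and not against other genes, called 0, with a smallest adjusted p of 0.25. Both alternatives rest on 2 degrees of freedom, so a list could hardly pass after adjustment over 44 lists. Their 0 calls thus do not show that no list shifted.

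**Figure D2:**
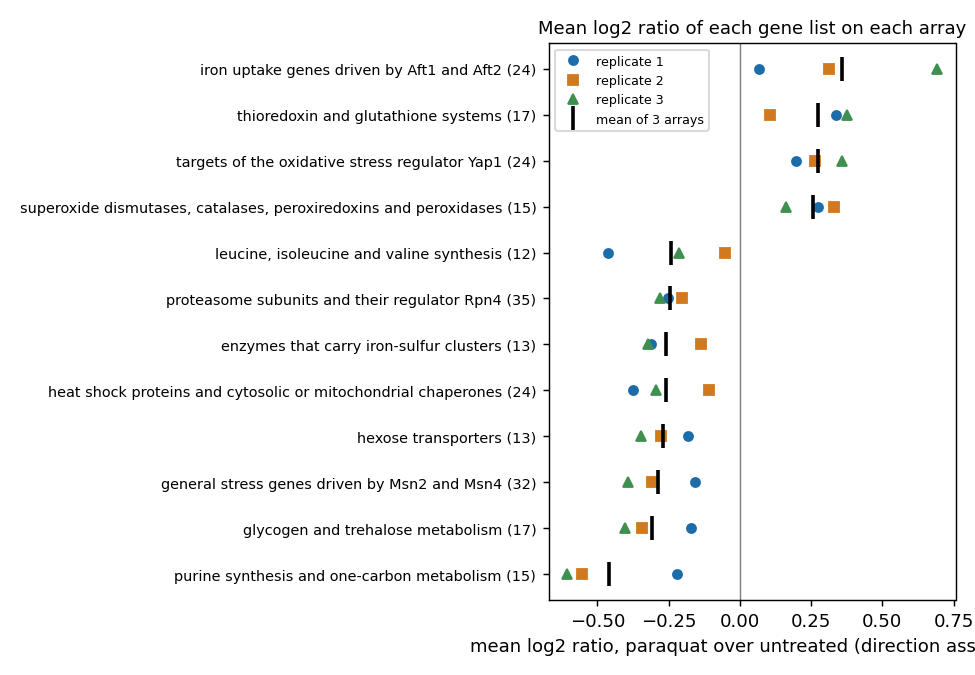
Mean log2 ratio over the measured members of each of the 12 called gene lists (x axis, paraquat over untreated, direction assumed) on each array, with the number of probes in parentheses and a bar for the mean of 3 arrays. The array means of the purine list were -0.22, -0.55 and -0.61, and those of the iron uptake list 0.07, 0.31 and 0.69.

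The list of superoxide and peroxide removal had a mean above 0, with members in both directions. The 15 measured members averaged 0.26 ± 0.09 (SD over 3 arrays; camera adjusted p = 0.00557, and adjusted p = 0.605 with an estimated correlation). Adjusted over the list alone, 5 rose, 1 fell and 9 did not pass, while over all genes 1 rose. GPX2, TSA1, SRX1, the sulfiredoxin that reactivates peroxiredoxins (0.76 ± 0.27, SD, n = 3 arrays), and TSA2 (0.73 ± 0.07) rose when adjusted over the list alone, and the cytosolic catalase gene CTT1 fell (-0.62 ± 0.53, and -0.32 without replicate 3). SOD1, the copper-zinc superoxide dismutase, had a mean of 0.41 ± 0.51 and SOD2, the mitochondrial manganese enzyme, of 0.33 ± 0.36, neither passing, and without replicate 2 these were 0.12 and 0.14. CTA1, the peroxisomal catalase, was at -0.17 ± 0.47, and its sign turned without replicate 2 and with the trend over the probe numbers removed. TSA1 and TSA2 are close paralogs and probe sequences were not used here.

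The lists of the thioredoxin and glutathione systems and of targets of the regulator Yap1 also had means above 0. The 17 measured thioredoxin and glutathione genes averaged 0.27 ± 0.15 (SD over 3 arrays; camera adjusted p = 0.000674, and adjusted p = 0.605 with an estimated correlation). In that list 4 rose when adjusted over the list alone, 0 passed over all genes and 13 did not pass: TRX2 at 0.89 ± 0.43, the glutaredoxin GRX2 at 0.82 ± 0.39, the thioredoxin reductase TRR1 at 0.62 ± 0.21, or 0.33 with the trend over the probe numbers removed, and TRX1 at 0.56 ± 0.18. Of 24 measured Yap1 targets, 6 rose adjusted over the list alone, 1 over all genes and 18 did not pass, with a mean of 0.27 ± 0.08 (camera adjusted p = 0.000165, and adjusted p = 0.605 with an estimated correlation). The 6 were GPX2, TSA1, TRX2, GRX2, SRX1 and TRR1, which the other redox lists also hold, so the 3 lists are not independent. YAP1 itself was at -0.09 ± 0.24 and the glutathione reductase gene GLR1 at -0.03 ± 0.21, neither passing and both with a sign that turned when 1 array was left out. On probes with a value in all 6 scans the Yap1 list had a mean of 0.18 and lost its call (camera adjusted p = 0.0906).

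The mean of the iron uptake list lay above 0 and that of the iron-sulfur enzyme list below 0, while most members of the former and all of the latter did not pass. Of 24 measured genes driven by Aft1 and Aft2, the iron-sensing activators, 22 had a mean above 0, and the list averaged 0.36 ± 0.32 (SD over 3 arrays; camera adjusted p = 3.91e-07, and adjusted p = 0.63 with an estimated correlation). Adjusted over the list alone, 4 rose and 20 did not pass, and over all genes 1 rose: FIT2, FIT1 at 0.86 ± 0.45, the siderophore transporter ARN1 at 0.72 ± 0.55 (0.42 without replicate 3) and the multicopper oxidase FET3 of high-affinity iron uptake at 0.60 ± 0.23. The list mean was 0.07, 0.31 and 0.69 on replicates 1, 2 and 3, and 0.19 without replicate 3. All 13 measured iron-sulfur enzyme genes had a mean below 0, averaging -0.26 ± 0.11 (camera adjusted p = 0.00332, and adjusted p = 0.605 with an estimated correlation), although 0 passed adjusted over the list alone or over all genes. The mitochondrial aconitase gene ACO1 was at -0.60 ± 0.46, LEU1 at -0.49 ± 0.38, RLI1 at -0.38 ± 0.18 and the homoaconitase gene LYS4 at -0.26 ± 0.01, or -0.0982 with the trend over the probe numbers removed. The iron-sulfur call was lost without replicate 3 (mean -0.23, camera adjusted p = 0.0549).

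The list of purine synthesis and one-carbon genes had the lowest mean of the 44 lists tested. Of 15 measured members, 14 had a mean below 0, and the list averaged -0.46 ± 0.21 (SD over 3 arrays; camera adjusted p = 6.15e-08, and adjusted p = 0.605 with an estimated correlation). Adjusted over the list alone, 5 fell and 10 did not pass, and 0 passed over all genes. ADE13, the adenylosuccinate lyase gene, was at -0.88 ± 0.14, ADE17 at -0.87 ± 0.57 and -0.57 without replicate 3, the serine hydroxymethyltransferase gene SHM2 at -0.79 ± 0.17, or -0.43 with the trend over the probe numbers removed, and ADE2 at -0.59 ± 0.39 (SD, n = 3 arrays).

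The lists of hexose transporters and branched-chain amino acid genes had means below 0, and their calls were lost under some settings. The hexose transporter list, which also holds the glucose sensor gene RGT2, had 13 measured members. They averaged -0.27 ± 0.08 (SD over 3 arrays, camera adjusted p = 0.00613, and adjusted p = 0.605 with an estimated correlation). HXT7 (-0.95), HXT2 (-0.91) and HXT6 (-0.81) fell adjusted over the list alone, 10 members did not pass, and 0 passed over all genes. HXT10 was at -0.35 ± 0.15. HXT6 and HXT7 are nearly identical genes, so their values may not be separate measurements. The transporter call was lost on high power scans alone (mean -0.17, camera adjusted p = 0.172) and without replicate 3 (mean -0.23, camera adjusted p = 0.0549), and the mean on low power scans alone was -0.48. The 12 leucine, isoleucine and valine genes averaged -0.24 ± 0.21 (camera adjusted p = 0.00809, and adjusted p = 0.605 with an estimated correlation), with 0 passing adjusted over the list alone or over all genes. LEU1, at -0.49 ± 0.38, and ILV3, at -0.30 ± 0.16, are also in the iron-sulfur list. The calls of those lists are thus not independent. ILV1, the threonine deaminase gene, was at -0.49 ± 0.43 and -0.28 without replicate 1. ILV5 was at -0.42 ± 0.63, with -0.17 without replicate 1 and -0.77 without replicate 2. The branched-chain call was lost without replicate 1 (mean -0.13, camera adjusted p = 0.199). It was also lost with the trend over the probe numbers removed (mean -0.13, camera adjusted p = 0.144), where ILV1, ILV5 and ILV3 were at -0.28, -0.24 and -0.17.

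The lists of general stress genes and of glycogen and trehalose genes, which share members, had means below 0. The 32 measured genes driven by Msn2 and Msn4, activators of the general stress response, averaged -0.29 ± 0.12 (SD over 3 arrays; camera adjusted p = 1.39e-06, and adjusted p = 0.605 with an estimated correlation). Adjusted over the list alone, 10 fell and 22 did not pass, and 0 passed over all genes. Among the 10 were the phosphoglucomutase gene PGM2 at -0.71 ± 0.18, the glycogen synthase gene GSY2 at -0.64 ± 0.36, or -0.42 with the trend over the probe numbers removed, the disaggregase gene HSP104 at -0.63 ± 0.30 and the glucokinase gene GLK1 at -0.57 ± 0.17. HSP12, a membrane-associated stress protein gene, was at -0.46 ± 0.77 and did not pass; its mean was -0.0195 without replicate 2 and -0.73 without replicate 1. The 17 glycogen and trehalose genes averaged -0.31 ± 0.12 (camera adjusted p = 5.8e-05, and adjusted p = 0.605 with an estimated correlation). Of these 7 fell adjusted over the list alone, including UGP1 at -0.60 ± 0.44 (-0.35 without replicate 3) and the glycogen phosphorylase gene GPH1 at -0.56 ± 0.08, 10 did not pass, and 0 passed over all genes.

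The chaperone and proteasome lists also had means below 0, with few members passing. HSP104, HSP42 and HSP26 are also in the general stress list, so the chaperone call is not independent of that one. The 24 measured heat shock protein and chaperone genes averaged -0.26 ± 0.14 (SD over 3 arrays; camera adjusted p = 0.00012, and adjusted p = 0.605 with an estimated correlation). Adjusted over the list alone, 7 fell and 17 did not pass, with HSP82 at -0.67 ± 0.25, its near-identical paralog HSC82 at -0.59 ± 0.06 and the HSP70 gene SSA2 at -0.57 ± 0.09, and 0 passed over all genes. Of 35 genes of the proteasome list, 31 had a mean below 0. The list averaged -0.25 ± 0.04 (camera adjusted p = 1.06e-05, and adjusted p = 0.605 with an estimated correlation). In it 1 gene fell adjusted over the list alone, the lid subunit gene RPN8 at -0.83 ± 0.44, 34 did not pass, and 0 passed over all genes. RPN5 was at -0.60 ± 0.09, RPN2 at -0.53 ± 0.31 and CDC48, which is not a proteasome subunit gene, at -0.47 ± 0.26.

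The other 32 tested lists did not pass, and leaving out 1 array moved the means of 29 of them by over 1.5 times or turned their sign, such as glycolysis (-0.0309 without replicate 1), thiamine (0.0743 without replicate 3) and NADPH sources (0.0409 without replicate 3). Adjusted over the list alone, some of their members did, named here after their values were seen, and 0 passed over all genes. FRE7 (-0.70) fell and CRS5 (0.69) rose in the copper list, SPG5 (-0.72) fell and SPI1 (0.58) rose in the stationary phase list, and PHO89 (-0.92) fell in the phosphate list. TPI1 (0.68) rose in the glycolysis list, IZH1 (0.75) in the zinc list and FPR2 (0.72) in the endoplasmic reticulum list. On replicates 1, 2 and 3 CRS5 was at 1.70, 0.37 and 0.0066, SPG5 at -1.24, -0.49 and -0.44 and FPR2 at 0.76, 0.11 and 1.30, so single arrays carried much of these means. Histones averaged 0.22 ± 0.10 over 9 probes (camera adjusted p = 0.0602) and the tricarboxylic acid cycle -0.16 ± 0.21 over 17 (camera adjusted p = 0.0748). Thiamine synthesis was at 0.14, glycolysis and fermentation at -0.12, RNA polymerase I and III subunits at 0.11, and the pentose phosphate and other NADPH sources at 0.10, where ZWF1, the first enzyme of that pathway, had a mean of 0.16 ± 0.31 (SD, n = 3 arrays), 0.26 without replicate 1 and -0.0156 without replicate 3, 0.068 with the trend over the probe numbers removed and 0.0282 on high power scans alone. The list of cytosolic ribosomal proteins, which by its naming pattern also took in RPP1, a ribonuclease P subunit gene, averaged 0.06 over 123 probes. Mitochondrial ribosomal proteins averaged 0.04 over 67 and the respiratory chain 0.01 over 31. Means were 0.12 for biotin, 0.10 for the zinc regulon, 0.07 for copper, 0.06 for endoplasmic reticulum folding, and 0.01 each for arginine, lysine and cell wall integrity genes. They were -0.08 for gluconeogenesis, -0.07 for polyamine transport, -0.06 for drug resistance, -0.06 for G2 to M genes, -0.05 each for ergosterol, histidine and aromatic, stationary phase, sporulation and G1 to S genes, and -0.04 for DNA damage and for daughter cell genes. The phosphate list and the alpha-cell list were at -0.03, hypoxic genes and ribosome assembly at -0.01 and sulfur and methionine genes at -0.00403. The 3 lists whose mean and median differed in sign were ribosome assembly (median 0.02), the respiratory chain (median -0.04) and arginine synthesis (median -6.48e-05). The list of genes expressed in a cells had 3 measured probes and was not tested (mean -0.26).

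Agreement was high between scans of an array and low between arrays. Across probes, which are not independent replicates, the high and low power scans correlated with Pearson r of 0.755, 0.821 and 0.810 on replicates 1, 2 and 3. These used only the 2271, 2680 and 3850 probes with a value in both scans, so they cover other probes than the correlations between arrays. Across the 5693 tested probes, r was 0.164 between replicates 1 and 2, 0.217 between 1 and 3 and 0.0254 between 2 and 3. Medians of the 16 nuclear chromosomes lay between -0.07 and 0.10 on every array. The 7 mitochondrially encoded probes had medians of -0.41, -0.95 and 0.49 on replicates 1, 2 and 3, and 7 of 7 were below 0 on replicate 2. The 11 genes of the list of M to G1 and daughter cell separation genes had list means of 0.11, 0.41 and -0.66 on the same arrays.

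**Figure D3:**
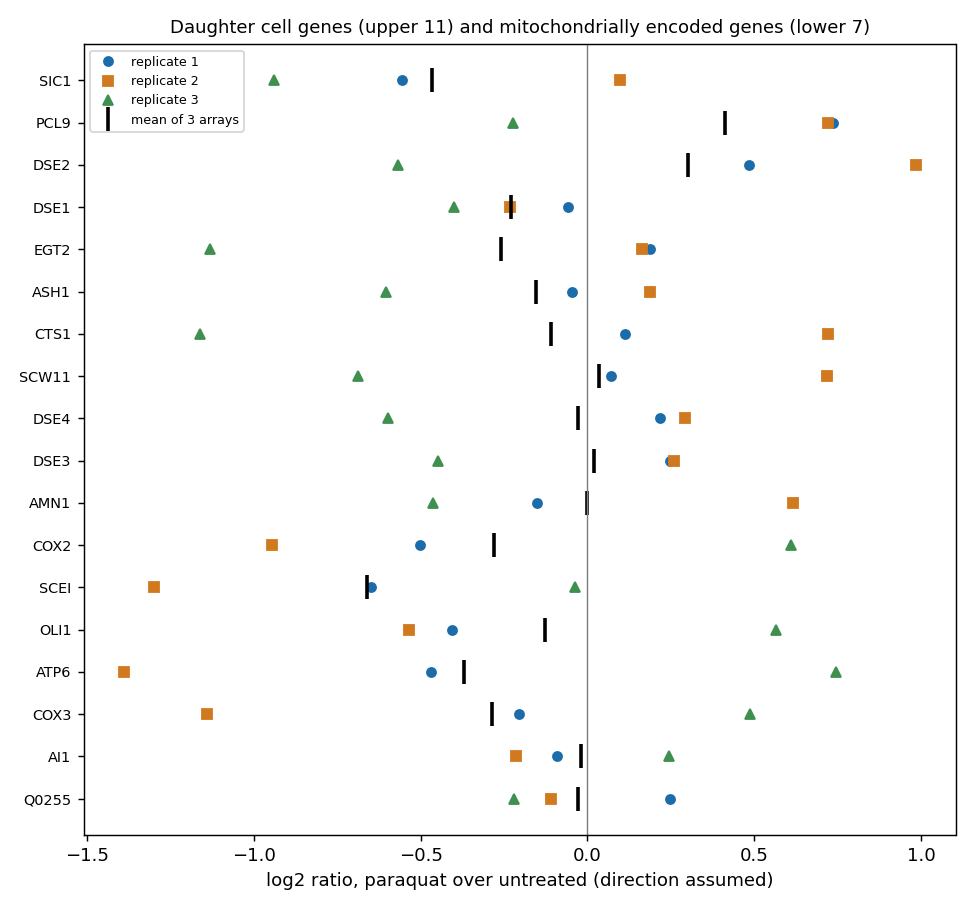
Log2 ratio of 11 daughter cell genes (upper) and 7 mitochondrially encoded genes (lower) on each array (x axis, paraquat over untreated, direction assumed), with a bar for the mean of 3 arrays. Replicate 3 lies below 0 for all 11 daughter cell genes, and replicate 2 lies below 0 for all 7 mitochondrial genes.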

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

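Removing the trend over the probe numbers, testing named probes alone and filling high power values with low power values were chosen only after the results were seen. The count of genes varied between settings, against 2 called by limma: 0 on high power scans, 0 with arrays centred, 0 with arrays centred and scaled, 0 without variance moderation, 0 against 1.2-fold, 0 with low power values filling gaps, 1 with the trend removed, 6 on at least 2 arrays, 6 with robust variance, 14 on named probes, 18 on low power scans and 19 on probes with all 6 scans. The settings with 14, 18 and 19 tested fewer probes (5218, 1978 and 1794) and still held both FIT2 and GPX2. Settings with 0 had between 134 and 602 probes at an unadjusted p under 0.05. Leaving out replicates gave 0 to 70 genes, and 2 to 9 past 2-fold on every array used, where fewer arrays ease that count; low power scans and centring gave 0 past 2-fold. Camera with an estimated correlation called 0 of 44 lists, against 12. For the proteasome list the estimate was -0.0224, below the preset 0.01, yet camera's unadjusted p was 0.0297, against 9.59e-07. Estimates for Yap1 targets (-0.0244), peroxide removal (-0.0625), hexose transporters (-0.0177) and iron-sulfur enzymes (0.00402) were also below 0.01. That argues against a higher correlation as the cause for these lists. The other called lists had estimates from 0.106 for branched-chain amino acids to 0.438 for iron uptake, with 0.295 for purines. For those the preset of 0.01 may be too low. With an estimated correlation camera also has 2 degrees of freedom, while the preset takes them from the number of probes. At the same test statistic that gives a larger p for every list, so 0 calls does not show that no list shifted. No further cause was tested. Fry, which tests a list against no change and not against other genes, called 0 as well. The means those tests left uncalled were 0.26 for peroxide removal, 0.27 for thioredoxin and glutathione, 0.27 for Yap1 targets, 0.36 for iron uptake, -0.26 for iron-sulfur enzymes, -0.29 for general stress, -0.31 for glycogen and trehalose, -0.26 for chaperones, -0.25 for the proteasome, -0.24 for branched-chain amino acids, -0.46 for purines and -0.27 for hexose transporters. Under all other settings run, 8 of these kept their call: peroxide removal, thioredoxin and glutathione, iron uptake, general stress, glycogen and trehalose, chaperones, the proteasome and purines. Camera takes no missing values, so lists were not run on at least 2 arrays. Arrays' signal over background was not analysed here, and a low power value stood for 1978 probes on every array.

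Calls were lost by hexose transporters on high power scans (-0.17), Yap1 targets on probes with all 6 scans (0.18) and branched-chain amino acids with the trend removed (-0.13), and gained by histones on named probes (0.22) and with gaps filled (0.22); the cause was not tested. Signs turned in results that passed under neither setting. On high power scans these were YAP1 (0.0019), glycolysis (0.00992) and lysine (-0.0268), and with gaps filled YAP1 (0.0019) and lysine (-0.0268). On low power scans they were GLR1 (0.0414), copper (-0.24), endoplasmic reticulum folding (-0.13), ribosome assembly (0.0434), the respiratory chain (-0.00345), hypoxic genes (0.0461), polyamine transport (0.0737), DNA damage (0.0248), cell wall (-0.0321), phosphate (0.0108) and G1 to S (0.12). On probes with all 6 scans they were ribosome assembly (0.0533), glycolysis (0.0126), lysine (-0.0159), hypoxic genes (0.0421), polyamine transport (0.0118), DNA damage (0.0420), cell wall (-0.0448), phosphate (0.00204) and G1 to S (0.0779). With the trend removed they were CTA1 (0.0526), GLR1 (0.0332), ribosome assembly (0.0145), the respiratory chain (-0.0130), polyamine transport (0.00943) and sporulation (0.0468).

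Leaving out each replicate gave these ranges of the mean where a call or a sign moved, with fewer arrays in each fit and the cause not tested. Calls moved for iron-sulfur enzymes (-0.32 to -0.23), branched-chain amino acids (-0.34 to -0.13), hexose transporters (-0.31 to -0.23), cytosolic ribosomal proteins (0.0171 to 0.11), RNA polymerase I and III (0.0293 to 0.21), the tricarboxylic acid cycle (-0.28 to -0.0929) and daughter cell genes (-0.27 to 0.26), the last called in opposite directions without replicate 2 and without replicate 3. Signs turned for CTA1 (-0.40 to 0.0646), GLR1 (-0.11 to 0.0940), YAP1 (-0.16 to 0.0492), ZWF1 (-0.0156 to 0.26), copper (-0.0318 to 0.13), endoplasmic reticulum folding (-0.0532 to 0.14), ribosome assembly (-0.11 to 0.10), the respiratory chain (-0.0144 to 0.0549), sulfur and methionine (-0.0240 to 0.0253), lysine (-0.0101 to 0.0301), arginine (-0.11 to 0.0761), ergosterol (-0.12 to 0.0279), hypoxic genes (-0.14 to 0.0849), polyamine transport (-0.13 to 0.00603), cell wall (-0.15 to 0.14), phosphate (-0.0529 to 0.00399), G1 to S (-0.16 to 0.0583), G2 to M (-0.15 to 0.0734), alpha-cell genes (-0.24 to 0.29) and stationary phase (-0.0796 to 0.00456).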

Other observations

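Every test of an explanation in this part was chosen or worded only after the result it measures was seen.

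A scan of 190 gene name families of at least 5 probes, made after the values were seen, put the ADE family of purine synthesis lowest. Its 10 probes averaged -0.47 ± 0.19 (SD over 3 arrays; camera adjusted p = 3.65e-05, and adjusted p = 0.993 with an estimated correlation), and this repeats the purine list. RPN proteasome genes averaged -0.26 ± 0.04 (camera adjusted p = 0.0469, and adjusted p = 0.993 with an estimated correlation). CCT chaperonin subunits at -0.31 ± 0.11, RPT proteasome ATPases at -0.32 ± 0.07 and RPC subunits of RNA polymerase III at 0.28 ± 0.23 did not pass (camera adjusted p = 0.0931 each). With the trend over the probe numbers removed, CCT, RPT and RPC were at -0.20, -0.22 and 0.21. Other families close to called lists did not pass either. ILV was at -0.33 (camera adjusted p = 0.174), or -0.18 with the trend over the probe numbers removed (camera adjusted p = 0.537). With camera adjusted p in parentheses, HXT was at -0.19 (0.22), HSP at -0.18 (0.395), PRE at -0.16 (0.467), GRX at 0.14 (0.633) and FRE at 0.04 (0.97). Single arrays carried some of these means, with -0.58, -0.03 and -0.37 for ILV, 0.34, -0.18 and 0.26 for GRX, -0.28, 0.23 and 0.16 for FRE and 0.03, 0.34 and 0.47 for RPC on replicates 1, 2 and 3.

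Daughter cell and most mitochondrial genes had opposite signs on replicates 2 and 3. On replicate 3 all 11 daughter cell genes lay below 0, with CTS1, the chitinase of cell separation, at -1.16 and EGT2 at -1.13. On replicate 2, 10 of 11 lay above 0, with CTS1 at 0.72 and DSE2 at 0.99 and the exception DSE1 at -0.23. Their medians were 0.11, 0.29 and -0.60 on replicates 1, 2 and 3, at the 76.1, 98.1 and 0 percentiles of 10000 random lists. Random lists hold unrelated probes, while the estimated correlation within the daughter cell list was 0.875. The list was also picked because its arrays disagreed, so the percentiles do not measure how unusual it is. Of 7 mitochondrially encoded genes, 7 lay below 0 on replicate 2 and 5 above 0 on replicate 3, with ATP6 at -1.39 on replicate 2 and 0.75 on replicate 3, and COX3 at -1.14 and 0.49. The exceptions on replicate 3 were SCEI at -0.04 and Q0255 at -0.22, and Q0255 was lower there than on replicate 2 (-0.11). Genes expressed in alpha cells averaged 0.19, 0.38 and -0.67, and the 3 measured genes expressed in a cells -0.01, -0.87 and 0.09.

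A trend over the probe numbers is argued against as the whole cause of this pattern, since without it the median on replicate 3 minus that on replicate 2 was still -0.897 for daughter cell genes and 1.48 for mitochondrial genes. An error of one scan is argued against for daughter cell genes, whose difference in the low power scans alone was -0.977. For mitochondrial genes it was 0.748 but rested on 1 probe on replicate 2, which leaves that error open. Cultures that differed in growth or in the share of newborn cells may explain part of it, the opposite values of alpha-cell and a-cell genes were not weighed, and no biological explanation was tested.

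The 12 called lists were weighed against a position trend, dim spots and dye. With the trend removed 11 were still called, which argues against it as the whole cause for those 11. A part of some means may still follow it. The general stress mean went from -0.286 ± 0.118 to -0.209 ± 0.139 and that of hexose transporters from -0.269 ± 0.083 to -0.206 ± 0.108. The iron uptake mean rose from 0.358 ± 0.315 to 0.388 ± 0.316. The branched-chain list went from -0.243 ± 0.207 to -0.131 ± 0.182 and lost its call, which leaves the trend open there. On probes with values in all 6 scans 10 were called, the Yap1 list fell to a mean of 0.178 without passing and the hexose transporters had too few probes. The number of samples with the treated culture in Cy3 was 0, so a dye effect cannot be told apart from paraquat for any list. Turning the sign of single arrays makes 4 patterns, too few for a share under 0.05: the real one was the 1 with as many genes (2, highest other 0) and the 1 with as many lists (12, highest other 8).

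Weak agreement between arrays was weighed against the same trend and against noise of dim spots. With the trend removed the highest correlation between arrays was 0.168, and that of replicates 2 and 3 turned from 0.0254 to -0.0397, so the trend is not the whole cause. Replicates 2 and 3 correlated at 0.00535 on probes with a low power value on every array, no higher than the 0.0209 on probes with none, which argues against dim spots for that pair. On the same bright probes replicates 1 and 2 correlated at 0.30 and replicates 1 and 3 at 0.287, against 0.00855 and 0.162 on probes with none, so dim spots may account for a part there and the rest stays open. Differences between the cultures were not tested.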
